A study of Solanum lycopersicum with 10 samples.

How the data were processed

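Fruit of tomato (Solanum lycopersicum, cultivar Micro-Tom) at the mature green stage were injected with calcium chloride or water and harvested 8 h or 24 h later, and a control completed the 5 groups, per the labels. The protocol in the labels also lists a harvest at 0 h; the labels of the control give no time and do not say whether it was injected, so ratios to the control may include effects of injection or wounding. Each group had 2 libraries, 10 in all, made from total RNA with a TruSeq RNA kit after column extraction and DNase digestion, per the labels' protocols. Nothing in the labels says whether the 2 libraries of a group came from separate plants. CASAVA is named in the submitters' processing notes. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here.

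The deposited values are group means in RPKM, per the file headers, so each value is the authors' mean over a group, corrected for gene length and library size, and no spread between libraries can be had from it. There were 4 tables, each restricted by the authors to genes they called differentially expressed, per the deposited legend: calcium against water at 8 h (1303 genes), calcium against water at 24 h (2153 genes), the control and both water groups (2410 genes), and the control and both calcium groups (2826 genes). Each deposited table also holds a signed fold, used here as a score of direction, and a difference of means. The deposited p-values are corrected for the false discovery rate, from Baggerley's test for the pairs of groups and from ANOVA for the sets of 3 groups, per the file headers. Checked on the values, every listed gene had a fold of at least 2, a difference of at least 20 RPKM and an adjusted p under 0.01, apart from 1 gene whose p is not a number. The deposited p is listed as 0 for 401 genes at 8 h and 578 at 24 h. A gene's mean for a group was identical in each table that held it, so the tables were joined by gene ID. A gene missing from a table did not pass its cut-offs, which does not show that it was unchanged. Such selection leaves out genes of low level and of small change.

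Gene names are the descriptions in the deposited tables. Of 4006 gene IDs, 0 matched the reference table of gene symbols used here, so no symbols or coordinates were added. Reads per library were not given in the files, so depth is unknown, and near-identical genes are uncertain where the authors' counting could have split shared reads.

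The comparisons, the gene lists, the rule for named genes and the first set of other settings were fixed before the data were examined. The planned test was a limma fit of log2(RPKM + 1) over all 10 libraries, with camera and fry for gene lists. It needs values of single libraries, so it could not be run, nor could the fit with a replicate block, the fits without 1 library, the other scalings of whole libraries or splits of the samples. In its place, a gene counts as called where the authors' table lists it. For the courses against the control, the authors' ANOVA calls were split by pairs of groups at a 2-fold ratio of means, which is a description and not a test.

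Direction of gene lists was tested with a two-sided Fisher's exact test of higher and lower counts in a list against the other genes of the same table, for lists with at least 5 listed genes, with Benjamini-Hochberg adjustment over the lists of a comparison and a threshold of 0.05. This test was chosen after the tables were seen. Correlation between genes could not be estimated without values of single libraries, so these p-values are too small. There were 29 lists, 5 by gene ID and 24 by words in the description. The written pattern for ethylene response factors also matched 14 descriptions such as superfamily proteins, which were left out of the main result; the list as written is an alternative. The test was tested on simulated tables: with the 5 largest lists drawn at 90% higher, it recovered 74.0% of them at 8 h (1303 genes, 21 lists) and 99.4% at 24 h (2153 genes, 24 lists), and it called 0.688% and 0.947% of lists with no bias. Genes were drawn independently and lists shared no genes. The recovery thus does not cover the smaller lists, and the rates of false calls do not cover correlated genes or overlapping lists.

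Log2 ratios were computed from the authors' means after adding 1 RPKM, which understates the change of genes at low level. Where calcium is compared with water, rises and falls are relative to water at the same harvest, not to the control. The rule for named genes took the 8 genes with the largest log2 ratio per direction for each calcium comparison at 1 time, 5 per direction for both times together and 3 for every other comparison, with a higher mean of at least 5 RPKM and a description. It added up to 4 genes per list with the smallest p and all members of the ripening list. The part of the rule that asked for agreement between single libraries could not be applied, and ties at a p of 0 were ordered by the size of the log2 ratio. Genes of the clock and desaturase families in the closing section, the caleosin and some of the genes that changed sides were chosen after their values were seen.

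Alternatives were other pseudocounts (0.1 and 5 RPKM), a minimum mean of 5 RPKM and, added after seeing the data, a 4-fold change, an adjusted p under 0.001, calcium means rescaled so that genes outside the calcium table had a median ratio of 1, the list pattern as written, and lists tested without the seed tissue markers. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.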

Results

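Transcript levels were measured by RNA sequencing in mature green fruit of the dwarf tomato cultivar Micro-Tom after calcium chloride or water had been injected into the fruit. There were 10 libraries in 5 groups of 2, namely calcium at 8 h and 24 h, water at 8 h and 24 h, and a control whose labels do not say whether it was injected. The study asked how calcium acts on the ageing of the fruit, and water was the vehicle at each harvest. No group received another salt, so effects of calcium, of chloride and of salt concentration cannot be told apart. The words after calcium thus mean after calcium chloride. The values were the authors' group means in RPKM (reads corrected for gene length and library size), given only for genes that passed the authors' own cut-offs in at least 1 of 4 tables. Together these tables held 4006 genes, 2028 of them with a mean in all 5 groups. Values of single libraries were not analysed here, so no mean below carries an SD and sequencing depth is unknown. A late embryogenesis abundant protein 5, Solyc09g075210.2, had the highest mean in every group, with an authors' mean of 33239 RPKM in the control and 8702 RPKM after calcium at 8 h.

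At 8 h, calcium sensors and kinases and WRKY factors were mostly higher in calcium-injected than in water-injected fruit, and wall enzymes and vascular markers were mostly lower. In the authors' deposited table, 762 genes were higher and 541 lower after calcium, 1303 in all. A fatty acid desaturase, Solyc12g100240.1, an enzyme class that puts double bonds into fatty acids, had an authors' mean of 1607 RPKM after calcium and 6.93 RPKM after water. A cortical cell-delineating protein, Solyc08g078900.1, went the other way, with 5.13 RPKM after calcium and 4670 RPKM after water. The authors' deposited table lists these differences as 232-fold and 911-fold.

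Among the other genes with the largest ratios at 8 h, 3 more desaturases stood higher after calcium. The authors' means of Solyc12g036520.1, Solyc12g100250.1 and Solyc12g049030.1 were 321, 333 and 366 RPKM after calcium, against 1.25, 2.16 and 3.71 RPKM after water. A cytochrome P450, Solyc04g083140.1, had 222 RPKM against 0.960 RPKM, and a carbonic anhydrase, Solyc02g067750.2, 115 RPKM against 0.0912 RPKM. An anthocyanidin synthase, Solyc10g076670.1, and an ACC oxidase, Solyc10g076680.1, had 120 and 98.7 RPKM after calcium. Their IDs are consecutive, as are those of Solyc12g100240.1 and Solyc12g100250.1, and values of such neighbours are uncertain where they share sequence, because the authors' counting could have split their reads. Among the genes furthest below water was a proline-rich protein, Solyc08g078920.1 (134 RPKM after water, 0.0415 RPKM after calcium). A cathepsin B-like protease, Solyc02g076980.2 (299 and 2.82 RPKM), and a fasciclin-like arabinogalactan protein 4, Solyc07g053540.1 (159 and 1.10 RPKM), came next. In the control these genes had 0.0502, 0.306 and 0.538 RPKM in that order, so the difference lay in the level after water. A gibberellin-regulated protein, Solyc02g089350.2 (279 and 2.69 RPKM), and an expansin-1, Solyc06g005560.2 (88.2 and 0.326 RPKM), followed. So did a gibberellin-regulated protein 2, Solyc02g083880.2 (621 and 14.4 RPKM). Their control means were 2.27, 3.13 and 2.95 RPKM in that order, so only the expansin was below the control after calcium. Expansins loosen cell walls and gibberellin-regulated proteins are small proteins often tied to growth. A second cortical cell-delineating protein, Solyc08g074480.1, had 3722 RPKM after water, 58.2 RPKM after calcium and 551 RPKM in the control.

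Genes of calcium perception were the clearest group on the higher side at 8 h. Of 27 calcium sensors and kinases in the table, 25 were higher and 2 lower after calcium (adjusted p = 0.000578, two-sided Fisher's exact test of direction against the other genes of the table, adjusted over 21 lists). Calmodulin-like proteins bind calcium and pass the signal on; Solyc04g058170.1 rose to 117 RPKM from 3.38 RPKM, and Solyc02g094000.1 to 60.7 RPKM from 1.36 RPKM. All 10 listed WRKY factors, regulators of stress and defence genes, were higher (adjusted p = 0.0204). Among them was WRKY transcription factor-b, Solyc05g015850.2 (177 and 2.57 RPKM). Among genes changed at least 4-fold the adjusted p was 0.0975 (Fisher's exact test), although every WRKY factor kept there was still higher. Of 14 ethylene response factors, 13 were higher and 1 lower (adjusted p = 0.0291), a call lost among genes changed at least 4-fold (0.245). It rests on leaving out false matches after the data were seen: the list as first written had 13 higher and 6 lower (unadjusted p = 0.484). Solyc02g077370.1 had 159 RPKM after calcium and 3.57 RPKM after water, and Solyc09g075420.2 had 293 and 28.6 RPKM.

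Cell wall genes made up the largest group on the lower side at 8 h. Of 36 pectin and wall enzymes, 30 were lower and 6 higher after calcium (adjusted p = 6.34e-06). A pectinesterase, an enzyme that removes methyl groups from pectin, had 75.7 RPKM after calcium and 900 RPKM after water (Solyc06g034370.1). Another pectinesterase, Solyc03g083730.1, rose to 728 RPKM from 46.3 RPKM, and a polygalacturonase, Solyc08g060970.2, which cuts pectin chains, rose to 88.7 RPKM from 8.55 RPKM. Of 19 vascular tissue markers, 17 were lower (adjusted p = 0.000171), including the fasciclin-like arabinogalactan protein 19, Solyc07g045440.1 (8.71 RPKM after calcium, 128 RPKM after water). All 12 photosynthesis genes were lower (adjusted p = 0.000171), as with the chlorophyll a-b binding protein 3C-like gene Solyc03g005760.1 (41.2 and 117 RPKM). The list of histones and cell division had 9 lower genes and 1 higher (adjusted p = 0.00777). Its members with the smallest p were mostly tubulins, the subunits of microtubules, such as Solyc04g077020.2 (167 RPKM after calcium, 828 RPKM after water).

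Seed storage genes moved with the wall and vascular genes at 8 h. All 9 listed seed tissue markers were lower after calcium than after water (adjusted p = 0.00148), with a median log2 ratio of -1.48. The median was -3.12 for the listed wall enzymes and -2.55 for the vascular markers. A 2S albumin, Solyc08g080490.2, had 517 RPKM after calcium and 1223 RPKM after water.

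Several lists leaned one way at 8 h without passing the test. All 8 listed genes of ethylene synthesis and perception and all 7 classical ripening regulators were higher after calcium (adjusted p = 0.0510 and 0.0742). These lists overlap, so they are not separate evidence. With every listed gene already higher, neither list could have leaned further, so these misses are not evidence against a direction. An ACC oxidase, Solyc07g049530.2, which makes ethylene from its precursor, had 4410 RPKM after calcium and 1044 RPKM after water, and an ethylene receptor, Solyc06g053710.2, had 237 and 60.0 RPKM. Pathogen defence had 16 higher and 3 lower genes (adjusted p = 0.0559), led by a pathogenesis-related protein, Solyc04g064880.2 (330 and 25.6 RPKM). Gibberellin and cytokinin genes had 4 higher and 10 lower (adjusted p = 0.0545), and cuticle and epidermis markers 7 higher and 14 lower (adjusted p = 0.0510). NAC factors (7 higher, 1 lower), calcium transport (5 and 1), abscisic acid and dehydration (5 and 1), auxin response (7 and 3), jasmonate and wound response (7 and 4), oxidative stress enzymes (14 and 9), phenylpropanoids (19 and 8) and sugar and starch genes (2 and 3) also missed the threshold. Lists with fewer than 5 listed genes had no test. These were carotenoid synthesis with 3 higher, aquaporins, ribosomal proteins and fruit softening with 3 lower each, carbon fixation with 1 higher and 2 lower, and heat shock and chaperones with 3 higher and 1 lower. Phytoene synthase 1, Solyc03g031860.2, the entry enzyme of carotenoid synthesis, had 139 RPKM after calcium and 47.4 RPKM after water.

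**Figure D1:**
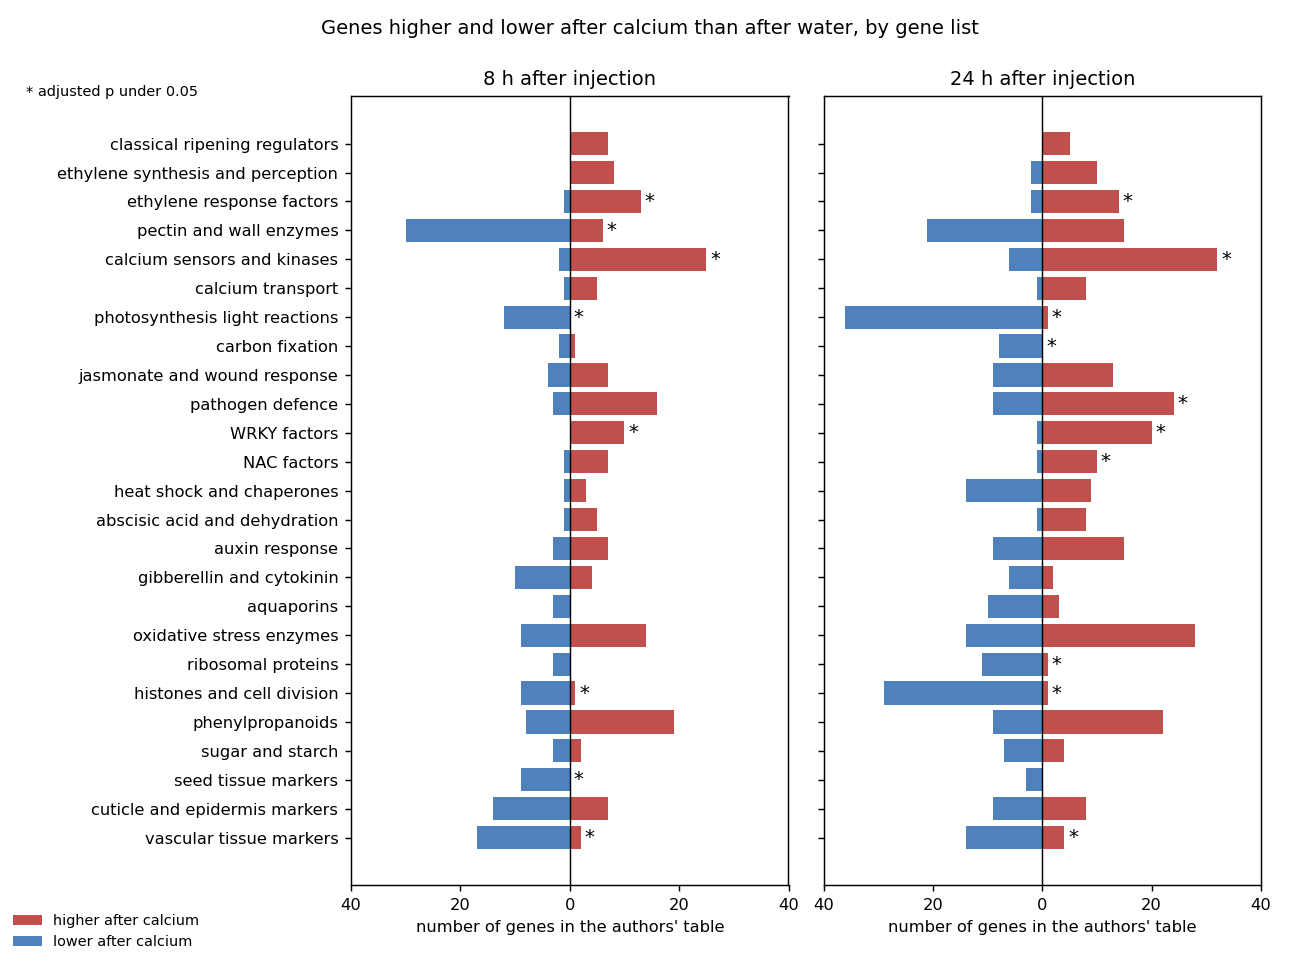
Number of genes in the authors' tables that were higher (right, red) or lower (left, blue) after calcium than after water at 8 h and 24 h, for each gene list with at least 5 genes in either table; stars mark lists with an adjusted p under 0.05 (Fisher's exact test against the rest of the table). Calcium sensors and kinases had 25 higher and 2 lower genes at 8 h, and photosynthesis genes 1 higher and 36 lower at 24 h.

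At 24 h the difference between the treatments took in more genes, with pathogen defence genes, calcium sensors and WRKY and NAC factors mostly higher after calcium, and photosynthesis genes and the list of histones and cell division mostly lower. The authors' deposited table had 1083 genes higher and 1070 lower after calcium, 2153 in all. An expansin-like protein, Solyc08g077910.2, had 3010 RPKM after calcium and 5.91 RPKM after water. An osmotin-like protein, Solyc08g080670.1, of a family of antifungal proteins, had 1202 and 1.85 RPKM, and a lipoxygenase, Solyc08g029000.2, which oxidises fatty acids, had 469 and 0.485 RPKM. Another lipoxygenase, Solyc08g014000.2, went the other way, with 26.4 RPKM after calcium and 1486 RPKM after water. The authors' deposited table gives 969-fold and 56.3-fold for the 2 lipoxygenases.

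The other genes with the largest rises at 24 h were a peroxidase 1, Solyc10g076240.1 (1028 RPKM after calcium, 1.95 RPKM after water), a calcium-binding EF-hand protein, Solyc03g031630.2 (329 and 0.413 RPKM), and a B12D-like protein, Solyc02g089140.2 (294 and 0.266 RPKM). A beta-glucanase, Solyc01g060020.2 (380 and 0.672 RPKM), and an ACC oxidase, Solyc07g026650.2 (1103 and 4.03 RPKM), completed them. Furthest below water were the cortical cell-delineating proteins Solyc08g074480.1 (15.0 RPKM after calcium, 5154 RPKM after water) and Solyc08g078900.1 (19.8 and 1577 RPKM). In the control they had 551 and 2.67 RPKM, so only the first was below the control after calcium. A BURP domain protein, Solyc05g005550.2 (2.01 and 223 RPKM), and the fasciclin-like protein 19, Solyc07g045440.1 (2.52 and 207 RPKM), were also lower than after water. So was a thiazole biosynthetic enzyme of the vitamin B1 pathway, Solyc07g064160.2 (32.7 and 1446 RPKM). A wound/stress protein, Solyc03g093360.2, had 8.73 and 401 RPKM, and a cellulose synthase-like C2 gene, Solyc10g083670.1, had 0.0469 and 40.1 RPKM.

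Regulatory and defence lists were higher after calcium at 24 h. Of 21 WRKY factors, 20 were higher and 1 lower (adjusted p = 0.000127 over 24 lists), with Solyc05g015850.2 at 223 RPKM after calcium and 0.883 RPKM after water. Of 38 calcium sensors and kinases, 32 were higher and 6 lower (adjusted p = 0.000127, but 0.0665 among genes changed at least 4-fold). Ethylene response factors (14 higher, 2 lower, adjusted p = 0.0139, but 0.581 at 4-fold), NAC factors (10 higher, 1 lower, adjusted p = 0.0344) and pathogen defence genes (24 higher, 9 lower, adjusted p = 0.0344) also passed. Pathogenesis-related protein 1a, Solyc01g106620.2, had 1560 RPKM after calcium and 19.8 RPKM after water. The list of ethylene response factors as first written, false matches included, had 16 higher and 6 lower (unadjusted p = 0.0514). Defence genes lost the call at 4-fold (adjusted p = 0.501) and with the calcium means rescaled (0.0809).

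Photosynthesis and growth lists were lower after calcium at 24 h. Of 37 genes of the light reactions, 36 were lower and 1 higher (adjusted p = 4.19e-09), with a median log2 ratio of -1.49. The chlorophyll a-b binding protein 3C-like gene Solyc03g005760.1 fell to 155 RPKM from 926 RPKM, and protein 13, Solyc12g011450.1, to 144 RPKM from 535 RPKM. All 8 carbon fixation genes were lower (adjusted p = 0.0139), including the Rubisco small chain Solyc03g034220.2 (1125 RPKM after calcium, 2366 RPKM after water). Of 30 genes in the list of histones and cell division, 29 were lower and 1 higher (adjusted p = 2.55e-07), as in a tubulin beta-1 chain, Solyc04g081490.2 (78.2 and 547 RPKM). Vascular tissue markers had 14 lower and 4 higher genes (adjusted p = 0.0434); a laccase 1a, Solyc04g054690.2, was among those higher (103 and 0.952 RPKM). Of 12 listed ribosomal proteins, 11 were lower and 1 higher (adjusted p = 0.0139), among them a 50S protein L27, Solyc11g068820.1 (56.8 and 138 RPKM), and a 30S protein S5, Solyc02g077990.2 (42.8 and 93.3 RPKM); 30S and 50S are names of bacterial-type subunits, as in plastids. Over the 62 ribosomal protein genes with both means, called or not, the median log2 ratio was 0.53, opposite in sign to the test. The calls of carbon fixation and ribosomal proteins were lost with rescaled calcium means (adjusted p = 0.0628 and 0.0751).

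Ethylene and ripening genes at 24 h were again higher after calcium than after water in most cases. For ripening regulators, the median log2 ratio to the control was 0.14 after calcium at 8 h (10 genes) and -0.36 at 24 h (8 genes). After water it was -1.36 at 8 h (9 genes) and -1.28 at 24 h (10 genes). Being higher than after water thus did not put this list as a whole clearly above the control. Ethylene synthesis and perception had 10 higher and 2 lower genes (adjusted p = 0.0663), and all 5 listed ripening regulators were higher (adjusted p = 0.0879), so neither list passed. The ripening list was too small to pass on the higher side. With all 5 genes higher, its unadjusted p was still 0.0622 (Fisher's exact test), so its miss says nothing about direction. An ACC synthase, Solyc01g095080.2, the enzyme before ACC oxidase, had 51.0 RPKM after calcium, 0.416 RPKM after water and 2.76 RPKM in the control. The ethylene receptor Solyc06g053710.2 had 324, 32.0 and 141 RPKM in the same order. Pigment and softening lists were too small to test. Both listed carotenoid genes were lower, a zeaxanthin epoxidase, Solyc02g090890.2 (62.3 RPKM after calcium, 126 RPKM after water), and a lycopene beta-cyclase 1, Solyc04g040190.1 (12.7 and 38.9 RPKM). Both genes listed under chlorophyll breakdown and plastid control were lower, with 46.9 and 124 RPKM for the stay-green protein Solyc08g080090.2. In the softening list, the pectinesterases Solyc07g064170.2 (68.9 and 1917 RPKM) and Solyc07g064180.2 (8.53 and 122 RPKM) were lower, and an expansin, Solyc06g051800.2, was higher (70.8 and 5.16 RPKM).

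The remaining lists did not pass at 24 h. Pectin and wall enzymes had 15 higher and 21 lower genes (adjusted p = 0.363), calcium transport 8 and 1, abscisic acid and dehydration 8 and 1, oxidative stress enzymes 28 and 14, phenylpropanoids 22 and 9, and jasmonate and wound response 13 and 9. Auxin response had 15 higher and 9 lower, gibberellin and cytokinin genes 2 and 6, aquaporins 3 and 10, heat shock and chaperones 9 and 14, sugar and starch 4 and 7, and cuticle and epidermis markers 8 and 9. A phenylalanine ammonia-lyase, Solyc03g036470.1, the first enzyme of phenylpropanoid synthesis, had 106 RPKM after calcium and 2.36 RPKM after water. A dehydrin, Solyc04g082200.2, had 1395 and 138 RPKM, and a sucrose synthase, Solyc12g009300.1, 1501 and 56.6 RPKM. Only 3 seed tissue markers were in the table, all lower, with no test. Over the 10 with both means, called or not, the median log2 ratio of calcium to water was -2.11, with 9 lower and 1 higher. No listed gene matched the patterns for chloroplast and mitochondrial genomes.

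The difference between calcium and water had the same direction at both harvests for most genes called at both. Of 863 such genes, 538 were higher and 297 lower after calcium at both times, 835 or 96.8% in all. Another 440 genes were called only at 8 h and 1290 only at 24 h, so this share covers only genes that passed the cut-offs at both harvests. By the mean of both log2 ratios, the lipoxygenase Solyc08g029000.2 (6.74), the P450s Solyc04g083140.1 (6.69) and Solyc07g052370.2 (6.34), the desaturase Solyc12g100240.1 (6.59) and peroxidase 1, Solyc10g076240.1 (6.34), led the higher side. The cortical cell-delineating proteins Solyc08g078900.1 (-7.91) and Solyc08g074480.1 (-7.15), the wound/stress protein Solyc03g093360.2 (-5.27), a pectate lyase, Solyc05g014000.2 (-5.07), and the fasciclin-like protein 4, Solyc07g053540.1 (-4.99), led the lower side. The 8 h and 24 h groups share no libraries.

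The other 28 genes called at both harvests changed sides, 21 from lower to higher after calcium and 7 from higher to lower. The cathepsin B-like protease Solyc02g076980.2 had 299 RPKM after water and 2.82 RPKM after calcium at 8 h, but 7.27 and 96.9 RPKM at 24 h. The expansin Solyc06g051800.2 had 169 and 15.5 RPKM at 8 h, and a membrane protein, Solyc04g011480.2, had 61.2 and 6.40 RPKM at 8 h but 3.77 and 101 RPKM at 24 h. In the opposite sense, a vacuolar processing enzyme-1b, Solyc08g065610.2, had 185 RPKM after water and 954 RPKM after calcium at 8 h, then 1776 and 614 RPKM at 24 h. Two-sided Fisher's exact tests of each list's direction at 8 h against 24 h gave no adjusted p under 0.05 over 20 lists. The smallest unadjusted p, 0.0367, was that of the wall enzymes (6 higher and 30 lower, then 15 and 21, adjusted p = 0.734). Genes called at both harvests were counted at each as if they were different genes, and many lists were small. These tests therefore do not show that directions stayed the same. The interaction itself could not be fitted without values of single libraries.

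**Figure D2:**
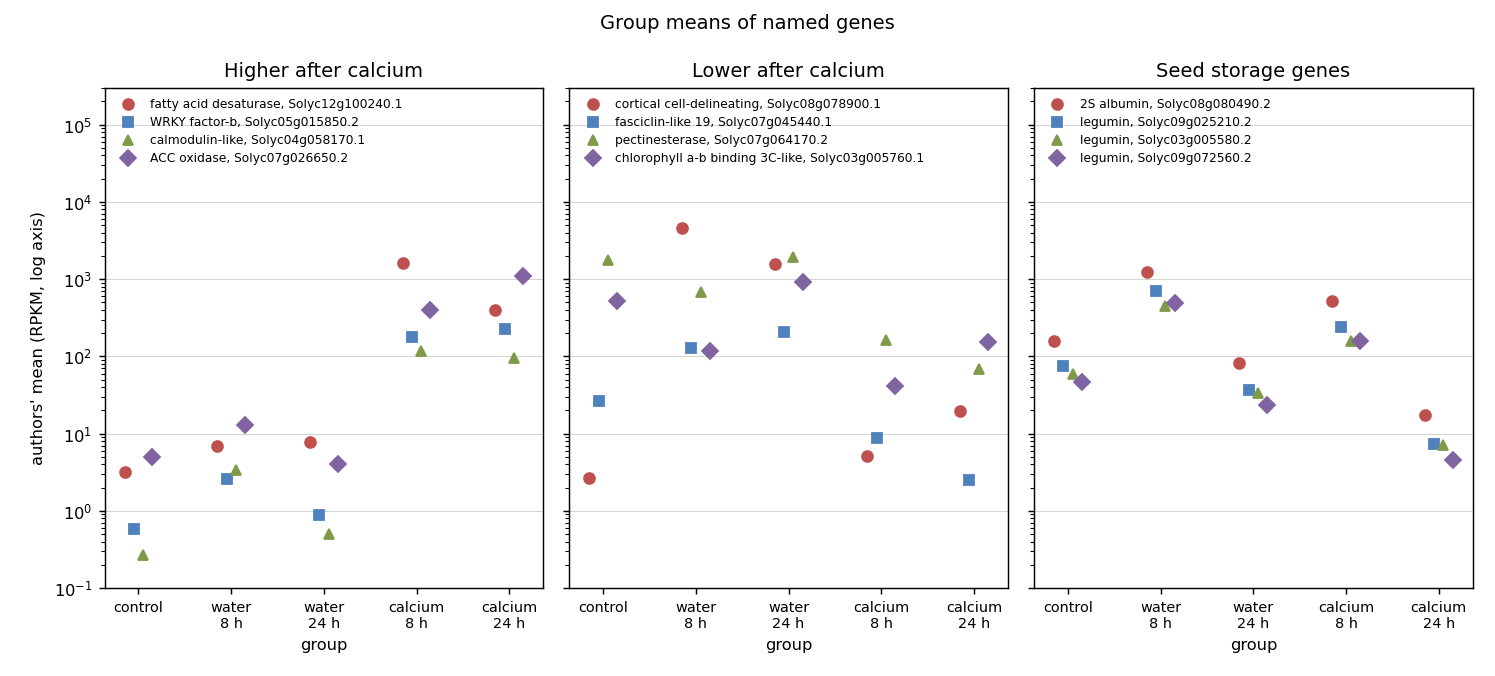
The authors' mean (RPKM, log axis) in each of the 5 groups for 4 genes higher after calcium, 4 genes lower after calcium and 4 seed storage genes; each point is 1 gene in 1 group. The desaturase Solyc12g100240.1 stood at 1607 RPKM after calcium at 8 h, and the 2S albumin Solyc08g080490.2 at 1223 RPKM after water at 8 h.

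Set against the control, genes higher after calcium mostly lay above it in calcium-injected fruit. At 8 h, 719 of the 762 higher genes had a control mean, and 635 of them were at least 2-fold above the control after calcium; 351 were also above it after water. At 24 h the counts were 923 of 1035 after calcium and 187 after water. The WRKY factor Solyc05g015850.2, with 0.576 RPKM in the control, is an example at both times. Genes lower after calcium differed between the harvests in where water stood. At 8 h, 482 of the 541 lower genes had a control mean. Of the 482, 294 were at least 2-fold above the control after water, and 211 at least 2-fold below it after calcium. Among the 294, 173 were within 2-fold of the control after calcium. The gibberellin-regulated protein Solyc02g089350.2 had 2.27 RPKM in the control, 279 RPKM after water and 2.69 RPKM after calcium. At 24 h, 889 of the 1070 lower genes had a control mean, and 638 of them were at least 2-fold below it after calcium. Of the 889, 515 were within 2-fold of the control after water and at least 2-fold below it after calcium. The pectinesterase Solyc07g064170.2 had 1777 RPKM in the control, 1917 RPKM after water and 68.9 RPKM after calcium.

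After water alone, wall, vascular, ribosomal and seed genes stood above the control at 8 h, and photosynthesis and heat shock genes below it. The authors' table of control and water groups listed 2410 genes by ANOVA, and 1184 of them were at least 2-fold above and 777 at least 2-fold below the control at 8 h, 1961 in all. The ANOVA does not say which pair of groups differs, so these pairwise counts describe means and are not calls, and effects of injection itself cannot be separated from those of water. All 101 ribosomal protein genes past 2-fold were above the control (adjusted p = 3.98e-22 over 24 lists, Fisher's exact test as before), with a median log2 ratio of 1.15. A 60S protein L10, Solyc06g082650.2, had 106 RPKM in the control and 318 RPKM after water. Of 35 wall enzymes, 33 were above the control (adjusted p = 3.73e-05), and 18 of 19 vascular markers (adjusted p = 0.00683). Seed tissue markers lay with them, 12 of 13 above the control (adjusted p = 0.0443), with a median log2 ratio of 2.89. The largest ratios were those of the cortical cell-delineating protein Solyc08g078900.1 (2.67 RPKM in the control, 4670 RPKM after water) and of a proline-rich protein, Solyc08g078870.1 (2.10 and 871 RPKM). On the lower side were 21 of 22 photosynthesis genes (adjusted p = 5.07e-07), 28 of 36 heat shock genes (adjusted p = 2.56e-05), all 6 carbon fixation genes (adjusted p = 0.0153) and 6 of 7 ripening regulators (adjusted p = 0.0425). A heat shock protein, Solyc03g082420.2, had 258 RPKM in the control and 1.76 RPKM after water, and a MADS box factor, Solyc06g069430.2, had 212 and 45.2 RPKM. Aquaporins (6 of 7 below, adjusted p = 0.0425), abscisic acid and dehydration genes (10 of 13 below, adjusted p = 0.0289) and WRKY factors (9 of 9 above, adjusted p = 0.0420) completed the 11 lists past the threshold.

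By 24 h after water, fewer genes stood apart from the control, 484 above and 316 below by at least 2-fold. Of the 1184 genes above the control at 8 h, 772 were within 2-fold of it at 24 h, and of the 777 below, 594 were. The list of histones and cell division had 27 of 28 genes above the control (adjusted p = 0.000133), for example a histone H3, Solyc10g008910.1 (37.2 RPKM in the control, 231 RPKM at 24 h). All 19 vascular markers (adjusted p = 0.000312) and 29 of 31 wall enzymes (adjusted p = 0.000254) were above it, while all 9 seed tissue markers were below it (adjusted p = 0.000786). All 27 heat shock genes, all 7 NAC factors and all 5 ripening regulators past 2-fold were below it (adjusted p = 1.15e-10, 0.00370 and 0.0212). A NAC domain protein, Solyc06g083850.2, had 51.8 RPKM in the control and 1.66 RPKM at 24 h, and an ethylene receptor, Solyc09g089610.2, had 59.8 and 1.40 RPKM. Cuticle and epidermis markers (14 of 17 below, adjusted p = 0.00154) and abscisic acid and dehydration genes (6 of 7 below, adjusted p = 0.0344) also passed.

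Between 8 h and 24 h after water, 772 genes were at least 2-fold higher and 1021 at least 2-fold lower at the later harvest. All 127 ribosomal protein genes were lower (adjusted p = 8.20e-32) and 35 of 36 photosynthesis genes higher (adjusted p = 2.54e-11). All 7 carbon fixation genes and 22 of 26 genes of histones and cell division were also higher (adjusted p = 0.0130 and 0.000177), and all 13 seed tissue markers were lower (adjusted p = 0.00567). A circadian clock gene described as late elongated hypocotyl, Solyc10g005080.2, had 84.9 RPKM in the control, 1.44 RPKM at 8 h and 77.8 RPKM at 24 h. A glucosyltransferase, Solyc02g063000.2, followed the same course (92.7, 0.372 and 102 RPKM), and a transcription factor, Solyc05g014590.2, the opposite one (1.76, 245 and 1.79 RPKM).

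After calcium, more genes stood apart from the control and more of them still did so at 24 h. The authors' table of control and calcium groups listed 2826 genes; 1475 were at least 2-fold above and 1060 at least 2-fold below the control at 8 h, and 1220 and 890 at 24 h. Of the 1475 genes above the control at 8 h, 1110 or 75.3% were above it at 24 h too, and of the 1060 below it, 730 or 68.9% remained below. The same shares after water were 29.6% and 21.8%, from a table with its own selection of genes; the difference was not tested. A beta-glucanase, Solyc01g060020.2 (0.191 RPKM in the control, 563 RPKM at 8 h and 380 RPKM at 24 h), and an S-locus-specific glycoprotein, Solyc07g062490.1 (2.97, 1760 and 1468 RPKM), were among the largest at 8 h. A hypoxia-induced protein, Solyc06g050870.2, had 0.498, 67.4 and 793 RPKM.

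At 8 h after calcium, 13 of 25 lists passed the direction test against the control. Calcium sensors and kinases (45 of 56 above, adjusted p = 0.00264), calcium transport (10 of 10 above, adjusted p = 0.0212), WRKY factors (21 of 23 above, adjusted p = 0.00395), ethylene response factors (21 of 26 above, adjusted p = 0.0499) and ribosomal proteins (51 of 56 above, adjusted p = 7.38e-07) lay on the higher side. A calcium-transporting ATPase 1, Solyc02g064680.2, which pumps calcium out of the cytosol, had 217 RPKM after calcium at 8 h and 32.1 RPKM after water. On the lower side were photosynthesis (39 of 40, adjusted p = 6.78e-13), heat shock (29 of 36, adjusted p = 2.55e-05), carbon fixation (7 of 8, adjusted p = 0.0312) and carotenoid synthesis (5 of 5, adjusted p = 0.0318). Histones and cell division (14 of 18, adjusted p = 0.0102), cuticle and epidermis markers (24 of 33, adjusted p = 0.00264), aquaporins (8 of 10, adjusted p = 0.0435) and sugar and starch (10 of 13, adjusted p = 0.0435) were there too. A chalcone synthase, Solyc05g053550.2, the entry enzyme of flavonoid synthesis, had 160 RPKM in the control and 0.419 RPKM after calcium, and a ferredoxin I, Solyc01g103920.2, had 652 and 5.73 RPKM. A non-specific lipid-transfer protein, Solyc10g075070.1, had 3819 and 59.4 RPKM.

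At 24 h after calcium, 8 lists passed against the control. Calcium sensors and kinases (41 of 46, adjusted p = 6.96e-05), calcium transport (9 of 9, adjusted p = 0.0396), WRKY factors (22 of 23, adjusted p = 0.000366) and pathogen defence (25 of 31, adjusted p = 0.0346) were above it. Heat shock (29 of 34, adjusted p = 1.00e-05), photosynthesis (16 of 17, adjusted p = 7.98e-05), cuticle and epidermis (23 of 29, adjusted p = 0.000366) and seed tissue markers (10 of 10, adjusted p = 0.000721) were below it. A class I heat shock protein, Solyc12g042830.1, had 279 RPKM in the control and 3.90 RPKM after calcium, and an MtN3-like protein, Solyc03g097580.2, a family of sugar transporters, had 91.9 and 1.82 RPKM. Between the harvests, 544 genes were at least 2-fold higher and 363 lower at 24 h after calcium. All 20 photosynthesis genes and all 13 of histones and cell division were higher (adjusted p = 0.000675 and 0.0156), and 10 of 11 seed tissue markers were lower (adjusted p = 0.00656). A PAR-1c protein, Solyc03g025670.2 (8.89 RPKM at 8 h, 692 RPKM at 24 h), and a Kunitz trypsin inhibitor, Solyc06g072210.1, of a family of defence proteins against insects (0.0917 and 71.9 RPKM), were among the largest rises.

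**Figure D3:**
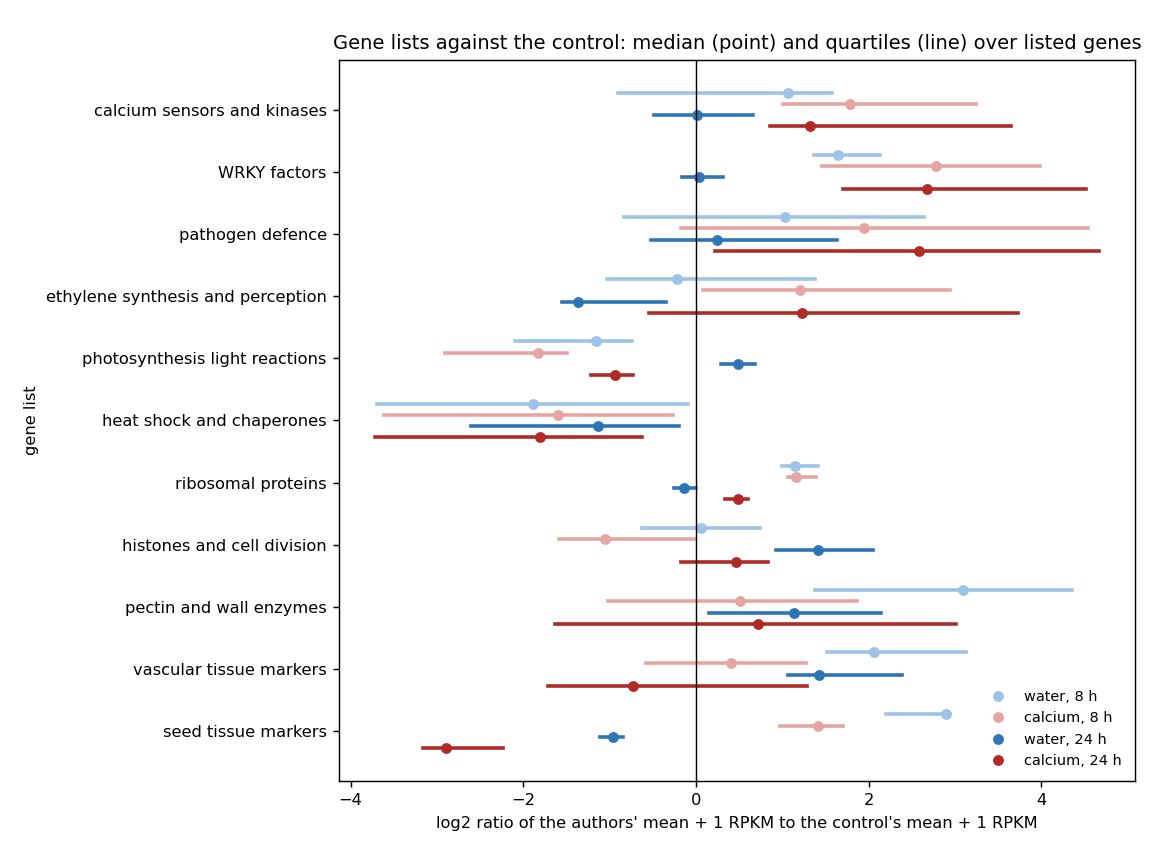
Median (point) and quartiles (line) over the genes of 11 lists of the log2 ratio of each group's mean to the control's mean, after adding 1 RPKM to both, over all listed genes with both means. Photosynthesis genes had medians of -1.16 and 0.48 at 8 h and 24 h after water, and of -1.84 and -0.93 after calcium.

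Seed storage transcripts were at different levels in several groups. Against the control, the direction after calcium at 8 h did not pass the test (8 above, 2 below, adjusted p = 0.326, Fisher's exact test). Relative to the control, the median over seed tissue markers was 7.43-fold after water at 8 h (14 genes), 2.67-fold after calcium at 8 h (12 genes), 0.513-fold after water at 24 h (14 genes) and 0.134-fold after calcium at 24 h (11 genes). The legumins Solyc09g025210.2, Solyc03g005580.2 and Solyc09g072560.2 had 75.1, 59.2 and 46.7 RPKM in the control and 7.26, 7.05 and 4.53 RPKM after calcium at 24 h. A caleosin, Solyc01g005410.2, in the same list but also made outside seeds in plants, had 64.7 RPKM in the control and 16.3, 6.49, 14.9 and 33.1 RPKM after water at 8 h, calcium at 8 h, water at 24 h and calcium at 24 h.

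All tests of lists rest on genes the authors selected, and genes are not independent replicates, so their p-values are too small by an unknown amount. Genes outside the calcium tables, known from the other tables, had a median log2 ratio of calcium to water of -0.17 at 8 h (1134 genes) and -0.14 at 24 h (614 genes), and the log2 ratios above were not corrected for it. Those genes had missed the cut-offs of the calcium tables, which keeps their ratios small.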

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

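The tests with a 4-fold change, an adjusted p under 0.001, rescaled calcium means, the list pattern as written and lists without seed markers were chosen only after the result was seen; the other pseudocounts and the minimum mean were planned.

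Requiring a 4-fold change lowered every count of genes. It left 573 of 1303 genes at 8 h and 1061 of 2153 at 24 h, 352 of 835 in the same direction at both times and 4 of 28 that changed sides. Against the control it left 750 of 1961 and 267 of 800 after water at 8 h and 24 h, and 1283 of 2535 and 1088 of 2110 after calcium. Between the harvests it left 589 of 1793 after water and 258 of 907 after calcium. Of the 1061 genes, 65.9% were higher after calcium, against 50.3% of all listed genes at 24 h. At 8 h the shares were 62.3% of the 573 genes and 58.5% of all listed genes. The cause was not tested. With fewer genes and more of the rest higher, a list on the higher side could lose its call at 4-fold without a weaker direction.

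Calcium sensors and kinases at 24 h lost their call at 4-fold (adjusted p = 0.0665, Fisher's exact test), as did WRKY factors at 8 h (0.0975), ethylene response factors at 8 h and 24 h (0.245 and 0.581) and pathogen defence at 24 h (0.501). With calcium means rescaled, carbon fixation (0.0628), ribosomal proteins (0.0751) and pathogen defence (0.0809) lost theirs at 24 h. Where a called list was tested with a pseudocount of 5 RPKM, a 4-fold change, an adjusted p under 0.001 or rescaled means, 57 results were the same and 8 weaker. That tally is a weak check, since some settings kept nearly the same genes. An adjusted p under 0.001 left 1279 of 1303 genes at 8 h and 2147 of 2153 at 24 h. The tally also leaves out the list pattern as written, with which ethylene response factors lost their call at both times. At 4-fold, some called lists kept fewer than 5 genes and had no test: 3 at 8 h, photosynthesis, histones and cell division and seed tissue markers, and 4 at 24 h, carbon fixation, NAC factors, ribosomal proteins, and histones and cell division.

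The number of lists past the threshold moved both ways. From 8 at 8 h it went to 11 with a pseudocount of 5 RPKM, 10 with rescaled calcium means, 7 with the list pattern as written, 7 without seed markers and 5 at 4-fold. The seed tissue markers were themselves among the lists called at 8 h, so leaving them out lowered that count by construction. From 10 at 24 h it went to 9 with the pattern as written, 7 with rescaled means and 6 at 4-fold. At 4-fold only 3 lists called at 8 h and 3 called at 24 h kept their call, and 2 and 3 others passed there alone. The direction of a listed gene could not reverse here: filters and pseudocounts keep its sign, and the rescaling removed medians of -0.17 and -0.14, less than a 2-fold change.

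No paired analysis was possible because only group means were given, so the planned fit with a replicate block could not be run. The other settings planned but not run for the same reason were no filter, median-ratio scaling, quantile normalization, no trend, only the groups compared, leaving out each library in turn, camera with estimated correlation, and fry.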

Other observations

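All tests in this part were chosen only after the result they concern had been seen, except the test of a delayed water response, whose bounds were written down before its value was computed; the handling of genes with no mean in it was settled afterwards.

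Fatty acid desaturases, which include the enzymes that make polyunsaturated lipids, were among the most raised genes after calcium. Of 12 such genes in any table, 9 were higher and 0 lower at 8 h, and 10 were higher and 1 lower at 24 h. The median log2 ratios over these listed genes were 5.47 and 5.25. Fisher's exact test against the rest of the table gave p = 0.0127 and 0.0115, unadjusted, for a family picked because it stood out. Some have consecutive IDs (Solyc12g100230.1, Solyc12g100240.1 and Solyc12g100250.1, and Solyc04g040120.1 and Solyc04g040130.1). Such neighbours may not be independent, so these p-values may be too small. Solyc12g044950.1 had an authors' mean of 1031 RPKM after calcium at 8 h and 77.9 RPKM after water, and Solyc04g040130.1 had 562 and 11.7 RPKM. A gene described as CER1, Solyc12g100270.1, whose relatives act in wax synthesis, had 177 and 1.32 RPKM.

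Some genes described as clock genes, chosen after their values were seen, shared a course in both treatments. The FKF-type gene Solyc01g005300.2 had 11.7 RPKM in the control, 49.1 and 42.6 RPKM after water and calcium at 8 h, and 19.2 and 14.7 RPKM at 24 h. GIGANTEA 1, Solyc04g071990.2, had 17.0 RPKM in the control, 39.3 and 42.6 RPKM at 8 h and 19.7 and 12.9 RPKM at 24 h. The ELF4-like gene Solyc07g041340.1 did not follow that course, with 22.0 RPKM in the control and 45.1 and 11.4 RPKM after water and calcium at 8 h.

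The first pattern was the lower level of wall enzymes after calcium at 8 h, and more seed tissue in the water libraries was a candidate explanation. Over all 39 wall genes with both means, called or not, the median log2 ratio was -2.79 (quartiles -4.17 and -1.32), and 23 of them lay below the lowest of 11 seed markers (-2.18). Of these genes, 36 wall genes and 9 seed markers were called at 8 h, so both sets rest mostly on genes picked for a difference of at least 2-fold. After water at 24 h the median log2 ratio to the control was 1.14 for wall genes and -0.96 for seed markers. These values argued against seed tissue as the whole cause, though a part could come from it. The share of other tissues, such as vascular tissue, was not tested. Over all 2437 genes with both means, the median was -0.0415 (SD 1.85), further from the wall genes than that SD. This argued against a common scaling of libraries as the whole cause, but only weakly. RPKM is already corrected for library size, and 1303 of these genes were picked for a difference of at least 2-fold.

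The second pattern was the difference in seed storage genes between groups, for which an unequal share of seed tissue might be the cause. If so, all markers should keep 1 ratio, with an SD of their log2 ratio to the control under 0.5, and an SD above 1 would argue against it. The largest SD was 0.858 once the caleosin was left out, so a share of tissue and regulation of these genes cannot be told apart. The caleosin was left out after its value was seen; with it the largest SD was 1.49, above the bound of 1.

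The third pattern was the set of genes away from the control at 8 h and back near it at 24 h, which might follow the time of day of harvest. Of 6 listed clock genes, 4 or 66.7% were shifted at 8 h and back at 24 h in both treatments, between the bounds of 50% and 80% set for the test. GIGANTEA 2, Solyc12g056650.1, had no mean after water and was counted as a failure. After calcium at 24 h it had 30.1 RPKM, more than 2-fold below the 84.1 RPKM of the control. Of all 2028 genes with every mean, 293 or 14.4% were shifted and back in this way, and the difference was not tested. That set leaves out GIGANTEA 2, and without it the share of clock genes would reach the upper bound. Time of day and time since injection cannot be told apart, because each harvest had 1 of each. The tables list only genes that changed, so clock genes that stayed level are not counted.

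A delay of the water response by calcium could also explain why 294 genes raised by water at 8 h were lower after calcium. The prediction made beforehand was that over 50% of them would stand at least 2-fold above the control after calcium at 24 h, and that under 25% would argue against it. Measured above it were 39, or 13.3% of the 294, which met the bound against a delay, but 141 had no mean after calcium at 24 h, and the share would be 61.2% if all of those stood above. Their absence from the table does not show that they did not, since 38 of the 141 were at least 2-fold above the control after calcium at 8 h and yet unlisted, 0 of them by 20 RPKM or more; delay and suppression thus cannot be told apart. Among the 153 genes with a mean, picked by being listed as changed, 40 were above the control after calcium at 8 h and 39, or 25.5%, at 24 h, so no net rise was measured.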
